A study of Mus musculus with 6 samples.

How the data were processed

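RNA from primary mouse fibroblasts was measured on 6 Affymetrix arrays, 3 of lines carrying the Delta9 allele of Lmna and 3 of wild-type (WT) lines. Per the labels' protocols, total RNA was extracted with Trizol, labelled with biotin by the manufacturer's 1-cycle kit and hybridised to 1 array per sample. Per the series design text, the lines were derived from siblings, taken at passage 3 and kept without serum for 72 hours before RNA was taken. That text calls the replicates independent, and neither it nor the labels say how many animals they came from, so the p-values measure the spread between these samples. The labels call the cells adult and the design text calls them post-natal; the difference was not resolved here.

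The deposited values are log2 probe set summaries for 45101 probe sets. The arrays' medians were 3.36 for Delta9 replicate 1, 3.37 for Delta9 replicate 2, 3.40 for Delta9 replicate 3, 3.43 for WT replicate 1, 3.40 for WT replicate 2 and 3.38 for WT replicate 3, so the table had been brought to a near-common scale before deposit. The summarisation method, its background correction and its normalization are not given in the sources used here. The log2 base was inferred from the range of the deposited values. The table holds no detection calls, so a dim probe set is described by its level and its rank among the genes tested. The number of arrays, 3 per group, limits the precision.

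The 64 control probe sets were left out of the tests and read as quality controls. Gene names came from the platform's annotation. Among the remaining probe sets, 34945 had 1 gene symbol, 932 had several and 9160 are unnamed here; 34741 of those with 1 symbol were matched by Entrez identifier to a RefSeq table of assembly GRCm38.p6, and no symbol had to be updated. That table was used only for names and for which genes lie next to each other. No genome build was stated for the array values, so no coordinates are given. Each of the 18193 genes was represented by the probe set of the highest mean over the 6 arrays.

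Delta9 was compared with WT by a linear model per gene in limma 3.58.1 under R 4.3.3, with empirical Bayes variances that follow the mean expression (lmFit and eBayes, trend). P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Differences are log2 of Delta9 minus log2 of WT, with the moderated standard error (SE). The deposited values were used as they stand, with no pseudocount and no filter. On simulated data with the real genes' means and spreads, in which 200 of the 18193 genes were changed, the model recovered 72.3% of genes changed by 1 log2 unit and 98.0% of those changed by 2 log2 units, and 5.73% of its calls were false; a shift of 0.3 log2 in 1 list was found in 100% of 20 simulations. These simulated genes varied independently, which real genes do not.

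Before the data were examined, 39 gene lists were written, covering matrix, signalling, stress, metabolism, positional and cell type markers. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 39 lists, with a threshold of 0.05. Camera with the correlation estimated from the data and fry, which tests whether a list's genes move on balance one way, were run as alternatives. The matrix and Wnt lists were written with knowledge of the published study of this allele, so their direction is not independent evidence.

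The genes named were also fixed beforehand: Lmna; the 12 genes of largest difference in each direction among those past the threshold whose groups did not overlap; where fewer passed, all of them and the 5 further genes of lowest p in each direction; up to 4 members past the gene threshold of each list past its own threshold or with at least 2 such members; and Lef1, Tcf7l2, Axin2, Col1a1, Col1a2, Col3a1, Fn1, Cdkn1a and Xist whatever their result. List members named beyond this rule are those among the lowest p in their list or markers of interest, and were chosen after their values were seen.

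Alternatives fixed beforehand were quantile normalization, leaving out the dimmest genes, the mean of a gene's probe sets, leaving out probe sets of the _x_at and _s_at types, no variance trend, robust variances, array weights, the replicate number as a block, other thresholds, each Lmna probe set on its own, the 1000 most variable genes for the similarity of the arrays, and leaving out each sample in turn. The split of the arrays by their poly-A spike-in signal, as a block and within its larger part, was added after seeing the data. So were the mean of the macrophage list as a covariate and a test of all probe sets. Also added then were t tests of the arrays' list means, over all arrays, within the 4 arrays of that larger part and without WT replicate 3. Figures were drawn with matplotlib 3.10.9.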

Results

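The series measured how fibroblasts with the Delta9 allele of Lmna, the gene of the nuclear lamina proteins lamin A and lamin C, differ in gene expression from wild-type fibroblasts of their siblings. Primary cells at passage 3 had been kept for 72 hours without serum, a treatment that slows proliferation. There were 3 Delta9 and 3 WT samples, each on its own array, with log2 expression of 18193 named genes.

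Lmna itself, on chromosome 3, was lower in Delta9 in 3 of 3 samples on the probe sets with a clear signal. The brightest, 1421654_a_at, read 8.67 ± 0.28 in WT and 6.71 ± 0.52 in Delta9 (log2, SD, n = 3), a 3.90-fold lower level with a difference of -1.96 (SE 0.28) and an adjusted p of 0.0899, which misses the threshold. Its 3 Delta9 values were 7.07, 6.95 and 6.11, against 8.35, 8.89 and 8.78 in WT. Probe set 1457670_s_at showed the largest difference, from 9.00 ± 0.37 in WT to 5.58 ± 0.21 in Delta9 (SD, n = 3). It fell by 3.42 log2 (SE 0.22), or 10.7-fold, and passed with an adjusted p of 0.00421 when all 45037 probe sets were tested. Probe set 1425472_a_at differed by -2.05 (SE 0.32). The dim 1426868_x_at differed by -0.54 (SE 0.17) and the dim 1452212_at by 0.22 (SE 0.16), so the 5 probe sets disagreed in size and, for 1452212_at, in sign. Where these probe sets lie relative to the altered part of the gene was not determined here. A probe set outside that part does not check the genotype labels.

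In Delta9 fibroblasts, 10 genes fell and 1 rose past the adjusted p of 0.05. Among those that fell were extracellular matrix genes: Fmod, the collagen-binding proteoglycan fibromodulin, dropped 4.46-fold (difference -2.16, SE 0.12, adjusted p 0.00337), and Matn4, the filament-forming matrilin 4, dropped 5.81-fold (-2.54, SE 0.12, adjusted p 0.00189). Matn4 was dim in Delta9, at 3.46 ± 0.08 (log2, SD, n = 3), so its fold may be only a lower bound. Igfbp2, an insulin-like growth factor binding protein, had the largest drop of the 10 at 9.56-fold (-3.26, SE 0.23). Gla, the lysosomal alpha-galactosidase A, was the gene that rose, from 5.41 ± 0.08 in WT to 7.08 ± 0.06 in Delta9 (log2, SD, n = 3), or 3.18-fold (adjusted p 0.0109). All 11 were separated between the groups, in 3 of 3 samples.

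The other genes that fell were of several kinds. Mkx, a transcription factor of tendon development also known as mohawk, differed by -2.77 (SE 0.26). Scube2, a secreted protein that helps release Hedgehog ligands, differed by -2.98 (SE 0.22), and Id3, an inhibitor of basic helix-loop-helix factors that is induced by BMP signals, by -1.30 (SE 0.14). Cpxm2, a carboxypeptidase-like protein, differed by -2.44 (SE 0.20), Adamtsl3, a matrix protein of the ADAMTS-like family, by -1.71 (SE 0.17), Gpsm1, a G-protein modulator, by -1.49 (SE 0.16), and Jcad, a cell junction protein, by -1.30 (SE 0.12). Their adjusted p ran from 0.0109 for Scube2 to 0.0487 for Gpsm1 and Id3. For the 5 genes with more than 1 probe set, none of the 11 other probe sets had the opposite sign, but the other ones of Gla (0.64 and 0.14) and of Jcad (-0.19), which were dimmer, differed by less; with the mean of its probe sets Gla differed by 0.82 and did not pass (adjusted p 0.0569).

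**Figure D1:**
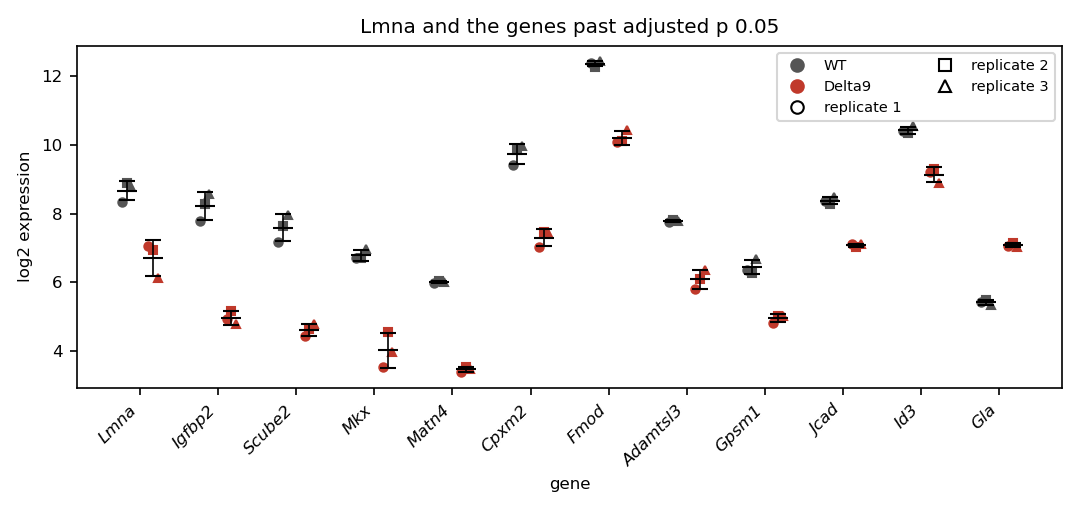
Log2 expression (vertical axis) of Lmna and of the 11 genes past the adjusted p of 0.05 (horizontal axis) in WT (grey) and Delta9 (red) samples. Symbols are single arrays by replicate number, and black bars show mean ± SD (n = 3). Every gene shown is separated between the groups, with Gla higher in Delta9 and the others lower.

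The genes next in line did not pass. Higher in 3 of 3 Delta9 samples were Ccl6, a chemokine of myeloid cells, with a difference of 3.72 (SE 0.44, adjusted p 0.0597), Hal, the histidine-degrading enzyme histidase, with 2.18 (SE 0.25), Arap2 with 1.46 (SE 0.19), Chchd10, a mitochondrial protein, with 1.37 (SE 0.19), and Gdpd1 with 1.12 (SE 0.18). Lower in 3 of 3 were the matrix proteoglycan Omd with -2.03 (SE 0.24), the Wnt receptor Fzd8 with -1.86 (SE 0.23), Calhm5 with -1.81 (SE 0.21), the pentraxin Ptx3 with -1.22 (SE 0.14) and Kcnip4 with -0.69 (SE 0.08). Kcnip4 was near the bottom of the scale, and Omd was dim in Delta9, at 3.41 against 5.44 in WT (log2). Across all genes, 1928 had an unadjusted p under 0.05, 826 higher and 1102 lower, where chance gives 910. The groups did not overlap for 17.3% of genes, where chance gives 10% for 3 samples against 3.

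The count of 11 genes moved with single samples, with a split of the arrays and with a covariate. Without Delta9 replicate 3 it was 81, without WT replicate 3 it was 4, without Delta9 replicate 1 it was 2, without WT replicate 2 it was 1, and without Delta9 replicate 2 or without WT replicate 1 it was 5. Poly-A spike-in transcripts, added to RNA before labelling, averaged 5.32 and 4.92 log2 on Delta9 replicate 3 and WT replicate 1, and 5.82 to 6.34 on the other 4 arrays. The gap between these parts was 0.50, little wider than the next gap of 0.40. With this split as a block, 149 genes passed, 47 higher and 102 lower, the 11 among them. Within the 4 arrays 61 passed, 10 higher and 51 lower, 9 of the 11 among them. The 3' to 5' difference of the Gapdh control probe sets was 0.25 and 0.23 log2 there in Delta9, against 0.49 and 0.51 in WT. For beta-actin it was 0.68 and 0.51 against 0.82 and 1.41. The comparison within these 4 arrays therefore cannot part genotype from this quality measure. On Delta9 replicate 3 and WT replicate 1 it was alike (Gapdh 0.57 on both, beta-actin 0.84 and 0.86). In the remaining pair, which allows no test, the 11 differed by at least 1.26 log2. Their direction there was fixed in advance, because the groups do not overlap for any of the 11 genes. With the mean of the macrophage markers as a covariate 3 passed, Igfbp2, Matn4 and Fmod, and the other 8, Gla among them, did not; the differences of the 11 stayed at 88.2% to 102% of their size (Gla 1.64, SE 0.15, against 1.67, SE 0.13).

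Matrix genes were lower in Delta9 as a group, which is the theme the published study of this allele is known for, so the lists' direction is not independent evidence. Of 67 measured matrix glycoproteins and proteoglycans, 49 had lower and 18 higher values, with a median difference of -0.27. With single samples left out it ran from -0.21 (without WT replicate 3) to -0.44 (without WT replicate 1), and it was -0.14 with the macrophage covariate. Over all genes 2 fell past the threshold, Fmod and Matn4. Adjusted over the list alone, 18 fell and 2 rose. Members named after their values were seen were Thbs4, a thrombospondin abundant in tendon, with -2.42 (SE 0.32), Prelp, a proteoglycan that binds collagen, with -1.95 (SE 0.25), and Eln, elastin, with -1.20 (SE 0.19). The list was lower by camera (adjusted p 1.51e-08), though with an estimated correlation its adjusted p = 0.385. The 36 collagen genes, 30 of them lower, had a median of -0.18 and a camera adjusted p of 7.46e-06 (adjusted p = 0.385 with an estimated correlation). With single samples left out the median ran from -0.15 (without Delta9 replicate 3) to -0.29 (without WT replicate 1), and it was -0.11 with the macrophage covariate. Over all genes 0 fell past the threshold (limma, 11 at an unadjusted p under 0.05), and 6 fell when adjusted over the list alone. Among these 6 were Col12a1 with -1.83 (SE 0.29), Col11a1 with -1.04 (SE 0.13) and Col6a1 with -0.74 (SE 0.14). The main fibrillar collagens had small differences: Col3a1 differed by -0.00 (SE 0.09), Col1a1 by -0.26 (SE 0.08) and Col1a2 by -0.23 (SE 0.13), and Fn1, fibronectin, by -0.31 (SE 0.18), none past the threshold. Genes for collagen processing and crosslinking, such as Crtap with -0.65 (SE 0.14), had a median of -0.25 over 28 genes (camera adjusted p 0.00165; adjusted p = 0.616 with an estimated correlation), and did not pass without Delta9 replicate 3 (adjusted p 0.221) or with the mean of the macrophage markers as a covariate, which was chosen after seeing the data (median 0.04, adjusted p 0.922). Macrophage markers went the other way between the groups, with a median of 0.95.

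Wnt genes were also lower as a group, again a theme of the published study and no independent evidence. Of 53 ligands, receptors and transducers, 41 had lower values, with a median of -0.18. Over all genes 0 passed (limma, 11 lower at an unadjusted p under 0.05). Adjusted over the list alone, 2 fell, the receptor Fzd8 and the agonist Rspo1 with -1.04 (SE 0.16). Rspo1 was dim, at 3.57 ± 0.23 in WT and 2.53 ± 0.21 in Delta9 (log2, SD, n = 3). This list was lower by camera (adjusted p 0.000335; adjusted p = 0.147 with an estimated correlation) and was the one list to pass by fry (adjusted p 0.00363). Of 29 canonical Wnt target genes 23 had lower values (median -0.14, or -0.23 without WT replicate 1 and -0.06 with the macrophage covariate; camera adjusted p 0.00169; adjusted p = 0.208 with an estimated correlation), and 7 fell when adjusted over the list alone, among them Fgf18 with -1.03 (SE 0.24) and Msx1 with -0.67 (SE 0.15). The antagonists were lower as well (28 genes, median -0.17, camera adjusted p 0.0213; adjusted p = 0.360 with an estimated correlation), with Sfrp1 at -1.35 (SE 0.33), and did not pass without Delta9 replicate 1 (adjusted p 0.0984). The Wnt genes named beforehand did not pass: Lef1 was dim, at 3.08 ± 0.07 in WT and 3.01 ± 0.07 in Delta9 (log2, SD, n = 3), Axin2, a common readout of the pathway, differed by -0.07 (SE 0.15), and Tcf7l2 by -0.18 (SE 0.25).

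Other signalling and patterning groups were lower by camera. TGF-beta and BMP genes had a median of -0.21 over 44 genes (adjusted p 0.000604; adjusted p = 0.385 with an estimated correlation); Id3 fell past the threshold over all genes, and 5 fell when adjusted over the list alone, including the ligand Bmp4 with -1.72 (SE 0.27) and the inhibitor Smad6 with -1.63 (SE 0.25). Hedgehog pathway genes, such as the co-receptor Boc with -1.34 (SE 0.43), had a median of -0.26 over 19 genes (adjusted p 0.00524; adjusted p = 0.385 with an estimated correlation). The 43 limb, face and body wall patterning factors, with Prrx1 at -0.78 (SE 0.16), had a median of -0.13 (adjusted p 0.00499; adjusted p = 0.592 with an estimated correlation), and did not pass without WT replicate 3 (adjusted p 0.0581). Cartilage and bone markers had a median of -0.13 over 21 genes (adjusted p 0.0225; adjusted p = 0.360 with an estimated correlation), with Comp, a matrix protein of cartilage and tendon, at -4.32 (SE 0.73, adjusted p over all genes 0.146), and did not pass without Delta9 replicate 2 (adjusted p 0.0555). With the mean of the macrophage markers as a covariate, the Hedgehog, patterning and cartilage lists did not pass (adjusted p 0.106, 0.189 and 0.0991).

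Genes of contraction and adhesion were lower by camera, but not when Delta9 replicate 3 was left out. The myofibroblast and smooth muscle list had a median of -0.47 (25 genes, adjusted p 0.00524; adjusted p = 0.616 with an estimated correlation), and its per-array means relative to the 6-array mean were 0.19, 0.03 and -0.82 in Delta9 replicates 1, 2 and 3, and 0.01, 0.19 and 0.40 in WT. YAP and SRF targets, with Ccn1 at -0.91 (SE 0.25), had a median of -0.28 (29 genes, adjusted p 0.0115; adjusted p = 0.616 with an estimated correlation), and integrin and focal adhesion genes one of -0.16 (39 genes, adjusted p 0.0446; adjusted p = 0.652 with an estimated correlation). These 3 lists did not pass without Delta9 replicate 3 (adjusted p 0.490, 0.314 and 0.543), nor with the mean of the macrophage markers as a covariate (0.357, 0.160 and 0.642). Within the 4 arrays of higher spike-in signal these 3 lists did not pass either (camera adjusted p 0.101, 0.101 and 0.263). The integrin list also did not pass without WT replicate 2 (0.0619) or WT replicate 3 (0.121), and it kept its call in 7 of 18 alternatives. The unfolded protein response list, with Hsp90b1 at -0.40 (SE 0.16), was lower (30 genes, median -0.19, adjusted p 0.0230; adjusted p = 0.616 with an estimated correlation), but not past the threshold without Delta9 replicate 3, WT replicate 2 or WT replicate 3 (adjusted p 0.314, 0.105 and 0.119), nor with the macrophage covariate (median 0.06, adjusted p 0.910). The skeletal muscle list was lower too (29 genes, median -0.29, adjusted p 0.0225; adjusted p = 0.701 with an estimated correlation), and lost its call without Delta9 replicate 2 (median -0.08, adjusted p 0.979) and without WT replicate 2 (0.556).

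Macrophage markers were higher in Delta9, unevenly between samples. Of the 29 macrophage and mast cell markers, 25 had higher values, with a median of 0.95; 0 passed over all genes (limma; 5 higher and 1 lower at an unadjusted p under 0.05) and 0 when adjusted over the list alone. Msr1, a scavenger receptor, differed by 1.54 (SE 0.34), Cd68, a lysosomal protein of macrophages, by 1.46 (SE 0.61) and C1qb, a complement subunit, by 1.19 (SE 0.49), whereas Tpsb2, a mast cell tryptase, differed by -0.40 (SE 0.11). The list was higher by camera (adjusted p 1.77e-06; adjusted p = 0.592 with an estimated correlation). Its per-array means were 0.33, 0.15 and 0.72 in Delta9 and 0.33, -0.23 and -1.30 in WT, so WT replicate 1 stood with the Delta9 samples. An exact two-sided permutation test of these means gave p = 0.2, where 3 samples against 3 cannot go below 0.1. The median was 0.32 without WT replicate 3 and 1.49 without WT replicate 1. WT replicate 3 also had the lowest 18S ribosomal RNA signal, 7.86 against 9.21 to 10.4 log2 on the other arrays, and the largest 3' to 5' difference of beta-actin, 1.41 against 0.51 to 0.86. The same sample had the highest matrix glycoprotein mean, 0.51, and the highest collagen mean, 0.31.

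Cell cycle and mitochondrial genes were higher by camera. The 54 cell cycle genes had a median of 0.26 (adjusted p 2.25e-05, and adjusted p = 0.616 with an estimated correlation), or 0.50 with the macrophage covariate. Pcna differed by 0.58 (SE 0.18) and Cenpa by 0.66 (SE 0.18). The list's per-array means were 0.27 and 0.50 in Delta9 replicates 1 and 2 and -0.38 in replicate 3, against -0.42, 0.07 and -0.04 in WT. The lowest, WT replicate 1 and Delta9 replicate 3, are the arrays of lower spike-in signal. Between them the median difference was 0.03, against 0.38 within the other 4 arrays. The list did not pass without Delta9 replicate 2 (adjusted p 0.142). The 50 oxidative phosphorylation genes had a small median of 0.10 (adjusted p 0.000176; adjusted p = 0.147 with an estimated correlation), with Sdhc at 0.40 (SE 0.14). Cdkn1a, the p53 target that encodes p21, differed by 0.33 (SE 0.30), and the 34 p53 target and senescence genes did not pass (median 0.11, adjusted p 0.113), but did, as higher, without Delta9 replicate 3 (0.00134) or WT replicate 3 (0.0104).

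**Figure D2:**
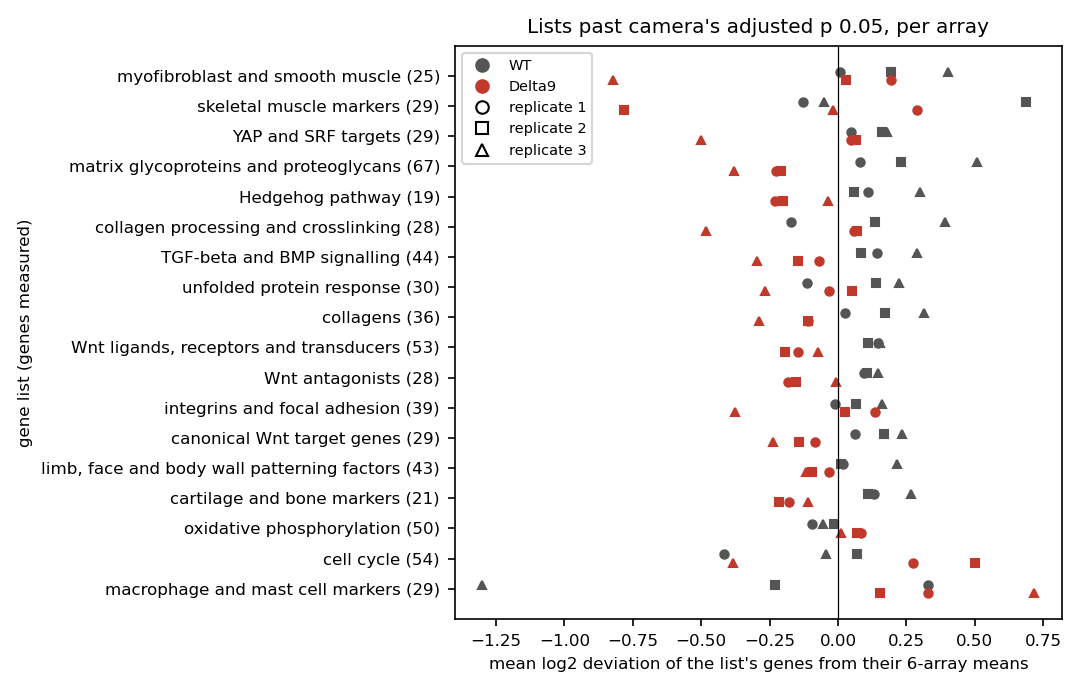
Mean log2 deviation of each list's genes from their means over the 6 arrays (horizontal axis), for the 18 lists past camera's adjusted p of 0.05 (vertical axis, with the number of genes measured). Points are single arrays, WT in grey and Delta9 in red, with symbols by replicate number; the macrophage list ranges from -1.30 in WT replicate 3 to 0.72 in Delta9 replicate 3.

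In all, 18 of the 39 lists passed by camera, 15 lower and 3 higher. None of the 18 held with an estimated correlation, whose adjusted p ran from 0.147 to 0.701, and 1 held by fry. With the mean of the macrophage markers as a covariate, 8 of the 17 lists other than the macrophage list did not pass. Lists were also gained, as 12 passed with this covariate and only 9 of them were among the 17. The other 21 lists had camera adjusted p from 0.0754 to 0.911; 7 of them passed when a single sample was left out, 6 of these without Delta9 replicate 3. Nuclear lamina and envelope genes (32 measured, median 0.02, mean -0.06, adjusted p 0.887) did not pass here or with any single sample left out; Lmna was the one member lower when adjusted over the list alone. The insulin-like growth factor axis (median -0.01, adjusted p 0.293) held Igfbp2 past the threshold and members on both sides, such as Irs1 at -0.92 (SE 0.15) and Igf2bp3 at 1.20 (SE 0.23). Positional Hox genes (33 measured, median -0.10, adjusted p 0.10) differed by at most 0.65 in size. The adjusted p of the fibroblast lists was 0.0947 for dermal papilla and papillary markers and 0.117 for reticular and adventitial markers. Of other cell types it was 0.256 for endothelial, 0.293 for keratinocyte, 0.840 for Schwann cell and melanocyte, and 0.911 for adipocyte markers, although Ednrb, an endothelin receptor among the Schwann cell and melanocyte markers, differed by 2.41 (SE 0.50). For stress and immune lists it was 0.20 for the interferon response, 0.293 each for inflammatory cytokines and for complement, 0.281 each for antioxidant and for DNA repair genes, and 0.197 for hypoxia and glycolysis. For remaining lists it was 0.0754 for the Notch pathway, 0.281 for cholesterol biosynthesis, 0.400 for matrix proteases and inhibitors and 0.478 for ribosomal proteins. For sex-linked genes it was 0.409. Xist was low in both groups, at 3.15 ± 0.16 in WT and 3.11 ± 0.10 in Delta9 (log2, SD, n = 3). The brightest Y-linked genes, Eif2s3y and Kdm5d, read 5.49 and 4.89 in WT and 5.51 and 4.90 in Delta9. On these genes the groups did not differ by sex. The dimmer Uty and Usp9y differed by -0.16 (SE 0.29) and -0.29 (SE 0.10).

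The arrays grouped only in part by genotype over all genes. The mean Pearson correlation across genes was 0.985 within and 0.980 between the groups, and genes are not independent replicates. Over the 1000 most variable genes it was 0.843 within and 0.761 between. Delta9 replicates 1 and 2 correlated best with each other (0.992), and WT replicates 1 and 3 each with WT replicate 2 (0.990 for both). Only Delta9 replicate 3 correlated best with an array of the other genotype. That was WT replicate 1 (0.987), the other array of lower spike-in signal, against 0.978 and 0.979 with Delta9 replicates 1 and 2. The first principal component held 44.7% of the variance and ran from WT replicate 3 (-41.1) to Delta9 replicate 3 (45.6), with Delta9 replicates 1 and 2 near 0 (-0.25 and -1.77). The second, with 30.7%, set Delta9 replicates 1 and 2 (33.7 and 25.7) apart from the other 4 arrays (-25.1 to -8.40).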

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

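The split by spike-in signal, the macrophage covariate and the test of all probe sets were chosen after seeing the data. The count of 11 genes (1 higher, 10 lower) stayed within 1.5 times under quantile normalization, without the dimmest genes, without _x_at and _s_at probe sets, without the variance trend, with robust variances and with a 1.5-fold minimum (9 to 12 calls), and with the mean of a gene's probe sets (8 calls, 0 higher). Over all 45037 probe sets 16 passed, a count of probe sets and not of genes, with several for Fmod and none for Gpsm1 or Id3. It was 3 (0 higher, 3 lower) at an adjusted p of 0.01, 48 (5 and 43) at 0.10, 139 (37 and 102) with array weights, 149 (47 and 102) with the spike-in split as a block, 61 (10 and 51) within its 4 arrays and 3 (0 and 3) with the macrophage covariate; leaving out each sample gave 1 to 81 calls, 0 to 12 higher and 1 to 69 lower. Apart from the thresholds and the fewer samples, the cause was not tested. With the replicate number as a block, 0 genes passed in limma (0 higher, 0 lower, and 1348 at an unadjusted p under 0.05) and 17 lists did. Same-numbered samples deviated from their group means with correlations of -0.40, 0.17 and -0.43, and not every sample correlated best with its own number. The largest correlation, 0.59, was between Delta9 replicate 3 and WT replicate 1, the arrays of lower spike-in signal. These values gave no sign of pairing by number. They cannot exclude it, because deviations from the mean of 3 samples must sum to 0, which constrains the correlations. The 11 called genes kept their sign in all 220 alternative values and their call in 143. Where a fit only leaves out samples the sign could not change, because the groups do not overlap for these genes. Lmna reversed on probe set 1452212_at (0.22) and passed on 1457670_s_at (-3.42), with the mean of its probe sets (-1.55), with array weights (-1.90), at a threshold of 0.10 (-1.96), with the spike-in block (-1.96) and within its 4 arrays (-1.83); leaving out samples gave -2.14 to -1.66, with a call without Delta9 replicate 3. The 18 list calls became 0 with an estimated correlation and 1 by fry, and were 12 to 21 otherwise. With an estimated correlation the adjusted p was 0.385 for collagens and for matrix glycoproteins, 0.147 for Wnt ligands and receptors, 0.208 for Wnt targets and 0.592 for macrophage markers; by fry it was 0.0840 for collagens and matrix glycoproteins, 0.0657 for Wnt targets and 0.486 for macrophage markers. With the macrophage covariate 8 of 17 lists lost their call, with adjusted p from 0.0991 to 0.922: collagen processing, the unfolded protein response, integrins, myofibroblast genes, patterning factors, YAP and SRF targets, Hedgehog genes and cartilage markers. For the skeletal muscle list, camera's direction relative to other genes changed without Delta9 replicate 2, while its median stayed below 0 (-0.08 against -0.29; adjusted p 0.979, with a range of 9.19e-05 to 0.979 over the samples left out). The within minus between correlation of 0.0048 was 0.0820 over the 1000 most variable genes and 0.0012 to 0.0062 without single samples, lowest without WT replicate 3. Pseudocounts were not tried because the table is in log2, and robust variances have no counterpart in camera. Dim genes, which the table gives no detection call for, limit what can be said of Lef1 and Axin2, and of Xist taken alone.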

Other observations

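The tests of the added gene lists, of dilution by macrophage RNA, of macrophage content, of WT replicate 3 and of the spike-in split were chosen only after the lists' values per array were seen, with those of the arrays' means added after camera's p-values were known; those of the genes next to Lmna and of other splits of the samples were fixed before their result was known. Genes known from tendon and fascia fibroblasts were lower in Delta9 as a group. A list of 30 such genes, written after Mkx, Fmod, Comp and Thbs4 had been seen and therefore no independent evidence, had 28 lower members and a median of -1.07, with 2 calls over all genes (Fmod and Mkx, both lower) and 19 lower when adjusted over the list alone. Tnmd, the tendon membrane protein tenomodulin, read 10.8 ± 0.22 in WT and 8.85 ± 0.66 in Delta9 (log2, SD, n = 3), and Prg4, the lubricating proteoglycan of joints and tendon sheaths, differed by -3.24 (SE 0.41). Camera gave an unadjusted p of 6.96e-22, and 0.00199 with an estimated correlation; 16 of the genes also stand in the matrix glycoprotein or collagen lists.

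Lysosomal genes showed the opposite direction. Of 44 measured genes in a list written after Gla had been seen, which includes Gla and 1 macrophage marker and is therefore no independent evidence, 33 had higher values, with a median of 0.38; Gla passed over all genes, and 13 rose when adjusted over the list alone. Ctsd, the aspartic protease cathepsin D, differed by 0.90 (SE 0.18), Ctsz, cathepsin Z, by 0.76 (SE 0.15), and Lamp1, a lysosomal membrane protein, by 0.40 (SE 0.11). Camera gave an unadjusted p of 1.46e-10, or 0.000105 with the macrophage mean as a covariate, and 0.0632 with an estimated correlation. Macrophage markers were higher in Delta9 too, and the covariate does not hold macrophage content fixed. A share of macrophage RNA in these differences is therefore not excluded. The unnamed probe set 1455869_at was also lower in Delta9, by a difference of -2.61 (SE 0.25, adjusted p 0.0280 over all probe sets).

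The lower matrix genes could have come from macrophage RNA diluting that of fibroblasts. The first test left this undecided: with the macrophage mean as a covariate the matrix glycoprotein list still passed (camera adjusted p 0.00530), but its median moved from -0.27 to -0.14 and kept 50.5% of its size, below the 66.7% asked for as evidence against dilution. A second test, added because of that outcome, asked whether dilution by 1 common factor is the whole cause: 13 of the 67 genes lay over 3 SE below the list's median, where 0.650 would be expected, which argues against it, while a part of the shift may still go with macrophage content. The covariate cannot single out macrophage content. Like the macrophage mean, the 18S ribosomal RNA signal was lowest in WT replicates 3 and 2 (7.86 and 9.21 log2) and highest in Delta9 replicate 3 (10.4). The change in the median under the covariate may go with either. The split of the arrays by spike-in signal, whose cause is not known, parts both genotypes alike. An equal shift of its parts therefore cancels out of the difference, and a block cannot test it. Over all arrays the arrays' list means differed by -0.54 (SE 0.14, t test p 0.0165), a test without the preset correlation. These means were -0.23, -0.21 and -0.38 in Delta9 and 0.08, 0.23 and 0.51 in WT. Within the 4 arrays of higher spike-in signal the list still passed (camera adjusted p 1.51e-09). Its mean differed there by -0.59 (SE 0.14), about as over all arrays. With 2 arrays against 2 the t test p was 0.0521, so an unequal shift is not excluded. The spike-in signal was not constant in these 4 arrays, at 6.34 and 6.27 in Delta9 and 6.14 and 5.82 in WT. Its range there, 0.52 log2, was wider than the gap of 0.50 that set the split, so these arrays do not hold the signal fixed. Among them the 3' to 5' differences of Gapdh and beta-actin were also lower in Delta9 than in WT. The camera p-values rest on the preset correlation, and the genotype stays open as an explanation.

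Whether WT replicate 3 alone set the higher macrophage markers cannot be told apart from a difference between the genotypes: without it the list passed at a camera adjusted p of 0.000978, which rests on the preset correlation (0.592 with an estimated one over all arrays), but its median fell from 0.95 to 0.32 and the arrays' means, which overlap, differed by 0.35 (SE 0.30, t test p 0.326). An unequal shift between the parts of the spike-in split stays open too, as within its 4 arrays the list passed (camera adjusted p 5.12e-08, at the preset correlation) but the means differed by 1.01 with an SE of 0.54 (t test p 0.204). Macrophage content that varied between cultures whatever their genotype cannot be told apart from a genotype effect, because the exact permutation p of the arrays' means was 0.2 and 3 samples against 3 cannot go below 0.1. Abundant macrophage markers such as Lyz2 and C1qb read 11.7 and 10.1 in WT and 12.7 and 11.3 in Delta9 (log2), so macrophages are a candidate source of RNA in both groups.

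The samples came from a mixed strain background, so variants linked to the Delta9 allele could have changed genes next to Lmna. The 50 measured genes nearest to Lmna in chromosome order had a median absolute moderated t of 0.82, at the 27.5th percentile of 10000 windows of 50 neighbouring genes, and 4 had an unadjusted p under 0.05, where the share over all genes gives 5.30. This argues against a change in most of these genes. A median over 50 genes would hardly move if linked variants changed a few of them, so such variants are not excluded. Single variants were not tested.

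The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes, 1 split, the real one, gave as many as its 11 calls, and the highest of the others gave 2. For lists, 1 split gave as many as the real 18, and the others gave 4 to 13. Camera at the preset correlation thus also called lists for groupings that mix the genotypes.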
